A study of Mus musculus with 30 samples.

How the data were processed

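Gene expression was measured in liver and subcutaneous fat of male mice aged 4 months that had been fasted overnight, per the labels. The mice carried a wild-type growth hormone receptor, a receptor truncated at amino acid 569 or at amino acid 391, a receptor mutated in its Box1 region, or no receptor (KO). Each of the 10 combinations of tissue and genotype holds 3 arrays, so 30 arrays were used. Per the labels' protocols, total RNA was isolated from frozen tissue with a column kit, labelled with biotin and run on Illumina bead arrays by a microarray facility. The background treatment, the normalization and the software of the authors are not given in the sources used here.

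The deposited value is a ratio, which the authors made by dividing each probe by its own median over the 15 arrays of a tissue. This is read from the values: the median was exactly 1 for all 46643 probes in liver and for all 46643 in fat, and the ratios carry 2 decimals between 0.01 and 168.6. The medians of the 30 arrays lay between 0.98 and 1.01, so the arrays had also been brought to a common level by a step that the sources used here do not describe. No absolute level remains in such a ratio. Signal over background is therefore unknown for every probe, the levels of different probes or of liver and fat cannot be compared, and an absent transcript cannot be told from a steady one. The lowest ratio, 0.01, occurred 10 times. For Sult2a2, whose WT and 569 livers all lie at this floor, differences are given as lower bounds with 0.01 set to 0.015, the top of its rounding interval, and these bounds cover the rounding alone.

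Probes were named through the platform annotation supplied with the data. It gives 1 gene symbol for 32794 probes, several for 55 and none for 13794, and 19406 genes were named. Of the named probes, 32722 had a gene identifier in the RefSeq table of assembly GRCm38.p6, which served for names and for the order of neighbouring genes alone, and 72 had not. Probe sequences and positions were not used here, so no genome coordinates are given. Members of near-identical families (Mup, Cyp4a12, Cyp2a, Cyp2b, Sult2a, Serpina1, Ces3) may share a probe, and their values are uncertain as to the copy measured.

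Ratios were transformed to log2 and fitted in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit, eBayes), with the 5 genotypes of a tissue in 1 fit and all 30 arrays in 1 fit for the contrasts between tissues. The tests were two-sided and the p-values were adjusted by the Benjamini-Hochberg method over all 46643 probes. Probes with an adjusted p under 0.05 are called changed. Each mutant was compared with wild type (WT). The 391 mutant was compared with 569, and KO with 391 and with Box1. A moderated F test covered any difference of the mutants from WT, and an interaction contrast tested whether a mutant's difference from WT differed between liver and fat. Choices of tests, comparisons, gene lists and named genes were made before the data were examined, except where the text says otherwise.

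The plan had to be changed in 3 respects once the unit was known. No offset was added before the logarithm, where 16 had been planned, because the ratios lie near 1. No filter on dim probes was applied, because a ratio holds no level, and all probes were kept. For genes with several probes, the probe with the largest SD over the arrays of the tissue was used in place of the one with the highest mean.

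Of 27 gene lists, 23 were tested in liver and 20 in fat with limma's camera at a preset correlation of 0.01 between genes, adjusted over all lists and the 4 comparisons with WT in a tissue. The same test was run with a correlation estimated from the data. For each list the members called over all probes are given, and beside them the members called with p-values adjusted over the list alone. Genes were named by a rule: 8 genes of the growth hormone axis always (Ghr, Igf1, Igfals, Socs2, Cish, Igfbp1, Igfbp2 and Igfbp3), up to 8 called genes with the largest rise and 8 with the largest fall per comparison with WT whose arrays did not overlap with WT, up to 5 each way in the comparisons between mutants, up to 3 each way per interaction, and up to 4 members of each list. Genes outside the rule are marked as chosen after their values were seen.

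The labels name the slide of each array. Each of the 5 slides held 6 arrays. WT and 569 shared a slide within each tissue, and so did 391 and KO, while the arrays labelled Box1 of both tissues shared the remaining slide. The comparisons 569 with WT and KO with 391 were thus made within a slide. For every other comparison each group lay on 1 slide, no fit with slide as a block could be made, and slide and genotype cannot be told apart. The labels do not say that each array is a separate animal, so p-values measure only the spread between these samples, which may be technical in part. The number of arrays, 3 per group, limits the precision of every estimate.

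Alternatives were quantile normalization within a tissue, array weights, fits on the arrays of the compared groups alone, and leaving out each array in turn. Added after the data were seen were a pseudocount of 0.1, a restriction to the probes with the larger SD, the muscle and lymphocyte content of the fat arrays as covariates, fits without fat 569 replicate 3, and fits without 2 liver arrays that held pancreatic transcripts. Also added then were the contrast of 391, Box1 and KO together with WT and the tissue contrast of KO with 391. The fits were tested on simulated arrays drawn from the residual spread of each of the 46643 probes, with known changes added in the arrays of 391 and compared with WT. In liver they recovered 25 of 50 probes changed by 0.5 (log2), 49 of 50 changed by 1, and all 50 changed by 2. In fat they recovered 19, 41 and 46 of 50 at these sizes. The simulated probes were drawn independently of each other, and 163 were called in fat. Adjustment is stricter where few probes are called, as in the real fat comparisons, so these shares may overstate what was recovered there. Other splits of the samples were drawn 100 at a time where more than 100 exist, and chance overlap of comparisons that share WT was simulated 20 times.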

Results

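The data set holds 30 bead arrays, 15 of liver and 15 of subcutaneous fat, with 3 arrays for each of 5 genotypes in each tissue. The genotypes are wild type (WT), growth hormone receptor truncated at amino acid 569 or 391, receptor mutated in Box1, and receptor removed (KO). As background, Box1 is the membrane-proximal segment through which the receptor engages the kinase JAK2, the 391 truncation removes the tyrosines on which STAT5 docks, and the 569 truncation removes a part of them. The comparisons ask what the liver and the fat lose as more of the receptor's signalling is taken away. All values are log2 of the deposited ratio of a probe to its tissue median. Group values are means ± SD of n = 3 arrays, and differences are fitted log2 differences ± SE. The medians of the arrays lay between 0.98 and 1.01. Signal over background is unknown. Of 60 gene results refitted without 1 array, 21 lost their call at least once, and the last part but one of the text names them. A genotype name below stands for the arrays so labelled.

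Ghr, the targeted gene, was measured by a pair of probes, and their positions relative to the deleted or mutated part are not given in the sources used here, so they may check none of the labels. The first Ghr probe gave liver ratios of 1.09, 0.92 and 1.27 in the arrays labelled WT, 0.95, 1 and 1.42 in those labelled 569, 0.68, 0.78 and 1.4 in those labelled 391, 0.3, 0.26 and 0.23 in those labelled Box1, and 1.51, 1.09 and 1.26 in those labelled KO. In fat the same probe gave 1.09, 1.97 and 1.47 (WT), 1.59, 1.41 and 0.63 (569), 1, 0.5 and 0.95 (391), 1.43, 0.96 and 0.44 (Box1), and 1.12, 0.29 and 0.46 (KO). The second Ghr probe gave liver ratios of 0.8, 0.61 and 1.14 (WT), 0.45, 0.54 and 1.22 (569), 1.07, 1.25 and 0.78 (391), 1.15, 1.28 and 0.96 (Box1), and 1.4, 0.81 and 1 (KO). Its fat ratios were 1, 2.05 and 1.64 (WT), 1.04, 1.52 and 0.13 (569), 0.46, 0.27 and 0.47 (391), 0.61, 0.44 and 1.13 (Box1), and 1.03, 0.68 and 1.26 (KO). In liver the first probe fell by 2.05 ± 0.23 in the arrays labelled Box1 (adjusted p = 2e-04). It differed by 0.23 from WT in those labelled KO (adjusted p = 0.78), so the probe is low in the Box1 label and not in the KO label. The second probe was called in no liver comparison with WT (0.45 and adjusted p = 0.65 in Box1, 0.34 and adjusted p = 0.76 in KO). In fat neither probe was called (KO against WT: −1.47 with adjusted p = 0.7 for the first, and −0.64 with adjusted p = 0.95 for the second).

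Liver of the 569 truncation against WT asks what the last part of the receptor contributes. Kyat3, an enzyme of tryptophan metabolism, fell by 2.79 ± 0.33 in the arrays labelled 569 (1.54 ± 0.80 in WT, −1.25 ± 0.30 in 569, adjusted p = 0.011). Wnk4, a kinase that regulates salt transport, fell by 0.64 ± 0.08 (adjusted p = 0.021), and Uhrf1bp1l fell by 0.67 ± 0.09 (adjusted p = 0.042). Igf1, the growth factor that liver makes under growth hormone, stood at 3.72 ± 0.20 against 4.27 ± 0.09 in WT (adjusted p = 0.52). Igfals, which encodes the subunit that retains IGF1 in plasma, stood at 2.98 ± 0.58 against 3.77 ± 0.16 (adjusted p = 0.42). Socs2 (−0.63, adjusted p = 0.84), Cish (−0.23, adjusted p = 0.97) and Igfbp1 (1.17, adjusted p = 0.85) were not called. Neither were Igfbp2 (−0.012, adjusted p = 0.998) and Igfbp3 (−0.48, adjusted p = 0.65).

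Among the 20 acute phase proteins measured in the arrays labelled 569, 0 were called over all probes, and 8 rose and 1 fell when adjusted over the list alone. The list as a whole was higher (camera adjusted p = 3.5e-12; adjusted p = 0.11 with an estimated correlation). Saa1 differed by 4.28 (adjusted p = 0.17), Lcn2 by 3.10 (adjusted p = 0.33) and Itih4 by 1.18 (adjusted p = 0.051). Lists that were lower in camera were the glutathione and xenobiotic enzymes (adjusted p = 0.0076; adjusted p = 0.67 with an estimated correlation), the cholesterol synthesis enzymes (adjusted p = 0.011; adjusted p = 0.67 with an estimated correlation), the endothelial markers (adjusted p = 0.0099; adjusted p = 0.6 with an estimated correlation) and the genes of fatty acid oxidation and ketogenesis (adjusted p = 0.047; adjusted p = 0.69 with an estimated correlation). No member of these 4 lists was called over all probes, and 1 glutathione enzyme fell when adjusted over the list alone. Of the 18 male-biased genes, 0 were called over all probes, against 1 up and 2 down adjusted over the list alone (list adjusted p = 0.45). In total, limma called 0 probes up and 4 down between 569 and WT in liver, and 3268 probes had an unadjusted p under 0.05. Both groups shared a slide. The count was 0 without 569 replicate 1 or replicate 2, 11 without 569 replicate 3, and 2, 8 and 10 without WT replicate 1, 2 and 3.

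Liver of the 391 truncation against WT asks what is lost with the STAT5 docking sites. Igf1 fell by 5.31 ± 0.18 in the arrays labelled 391 (4.27 ± 0.09 in WT, −1.04 ± 0.28 in 391, adjusted p = 1e-10), and its second probe fell by 4.14. Igfals fell by 4.23 ± 0.22 (adjusted p = 2.9e-08). Socs2 and Cish, feedback inhibitors that STAT5 induces, fell as well (−2.94 ± 0.43, adjusted p = 0.0024, and −1.93 ± 0.43, adjusted p = 0.032). The other Socs2 probes were not called in 391 (0.0023, adjusted p = 0.997, and 0.031, adjusted p = 0.963), nor in Box1 or KO. The call of Cish was lost in 5 of 6 refits without 1 array, and that of Socs2 in 0. Igfbp1, an IGF-binding protein of the fasting liver, rose by 3.80 ± 0.81 (adjusted p = 0.027), and Igfbp2 rose by 1.12 ± 0.24 (adjusted p = 0.027), calls that were lost in 3 and 4 of 6 such refits. Of the 21 measured genes of the growth hormone and IGF axis, 4 rose and 5 fell (5 and 5 adjusted over the list alone). The list was lower in camera, although its median was 0.03 (adjusted p = 0.029; adjusted p = 0.42 with an estimated correlation).

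Genes that male livers express more strongly fell together in the arrays labelled 391. Of 18 measured, 10 fell and 0 rose (14 and 1 adjusted over the list alone), with a median of −2.02 (camera adjusted p = 6.2e-33; adjusted p = 0.0012 with an estimated correlation). Serpina1e, an alpha-1-antitrypsin, fell by 7.18 ± 0.16 (6.78 ± 0.03 in WT, −0.40 ± 0.07 in 391, adjusted p = 5.3e-13). The fatty acid hydroxylase Cyp4a12a fell by 6.06 ± 0.32 (adjusted p = 2.9e-08), the urinary protein Mup2 fell by 4.96 ± 0.33 (adjusted p = 4.7e-07), and the organic anion carrier Slco1a1 fell by 4.12 ± 0.16 (adjusted p = 8.3e-10). Of 26 female-biased genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 8e-08; adjusted p = 0.0015 with an estimated correlation). The sulfotransferase Sult2a2, at the lowest printed ratio, 0.01, in all WT and 569 livers, rose by 6.90 as printed and by at least 6.32 if 0.01 stands for up to 0.015 (adjusted p = 1.1e-15, which rests in part on arrays at the floor that show no spread). Sult2a1 rose by 4.63 ± 0.13 (adjusted p = 6.6e-12), Cyp2b13 by 6.15 ± 1.17 (adjusted p = 0.014) and Cyp2a4 by 2.66 ± 0.27 (adjusted p = 5.9e-05).

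Genes of fatty acid uptake and lipid droplets were higher in the arrays labelled 391. Of 22 measured, 4 rose and 0 fell (7 and 0 adjusted over the list alone; camera adjusted p = 1.2e-04; adjusted p = 0.3 with an estimated correlation). Lipoprotein lipase Lpl rose by 3.04 ± 0.28 (adjusted p = 2.7e-05), the lipoprotein receptor Vldlr by 2.13 ± 0.26 (adjusted p = 4.9e-04), and the adipogenic transcription factor Pparg by 1.01 ± 0.17 (adjusted p = 0.0059). In gluconeogenesis and fasting response, 4 of 17 rose (10 adjusted over the list alone), among them the aminotransferase Gpt by 0.82 and Foxo1 by 0.64 (list adjusted p = 1.1e-04; adjusted p = 0.34 with an estimated correlation). In oxidative phosphorylation, 7 of 33 rose (20 adjusted over the list alone), with a median of 0.44, among them Cox5b by 0.65 ± 0.15 (list adjusted p = 5.7e-11; adjusted p = 0.41 with an estimated correlation). Among the acute phase proteins, 5 of 20 rose and 0 fell (8 and 1 adjusted over the list alone), with Itih4 up by 1.60 ± 0.17, Serpina3n by 1.78 ± 0.22 and Saa1 by 3.32 ± 0.80 (list adjusted p = 0.023; adjusted p = 0.67 with an estimated correlation). The epithelial markers were lower as a list, with 0 of 14 members called over all probes and 1 up and 3 down adjusted over the list alone (adjusted p = 0.032; adjusted p = 0.3 with an estimated correlation).

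Other large changes in the arrays labelled 391 were those of Hamp2, a member of the hepcidin family, up by 5.78 ± 0.37 (adjusted p = 2.8e-07, with 1 WT array at the floor, so its size is uncertain), the trypsin inhibitor Spink1, up by 5.14 ± 0.35 (adjusted p = 4.9e-07), and the carboxylesterase Ces3b, down (−5.35 ± 0.31). Pancreatic transcripts were present in 391 replicates 2 and 3, where 14 and 12 of 14 pancreatic markers exceeded 1 (log2), against 0 of 14 in each other liver array. Clps stood at ratios of 56.85 and 16.4 there and Cela2a at 42.03 and 19.59, and these pancreatic genes were chosen after their values were seen. In total 691 probes rose and 199 fell between 391 and WT, of which 137 and 93 changed at least 2-fold, and 678 genes were named by them. Group and slide were confounded here. The count of 890 was 1302 without both arrays that held pancreatic transcripts (500 of them shared; 1 array labelled 391 was left, with the spread taken from the other groups), 506 without 391 replicate 1, 379 without WT replicate 2, 401 without WT replicate 3, and 260 in a fit of these 6 arrays alone.

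**Figure D1:**
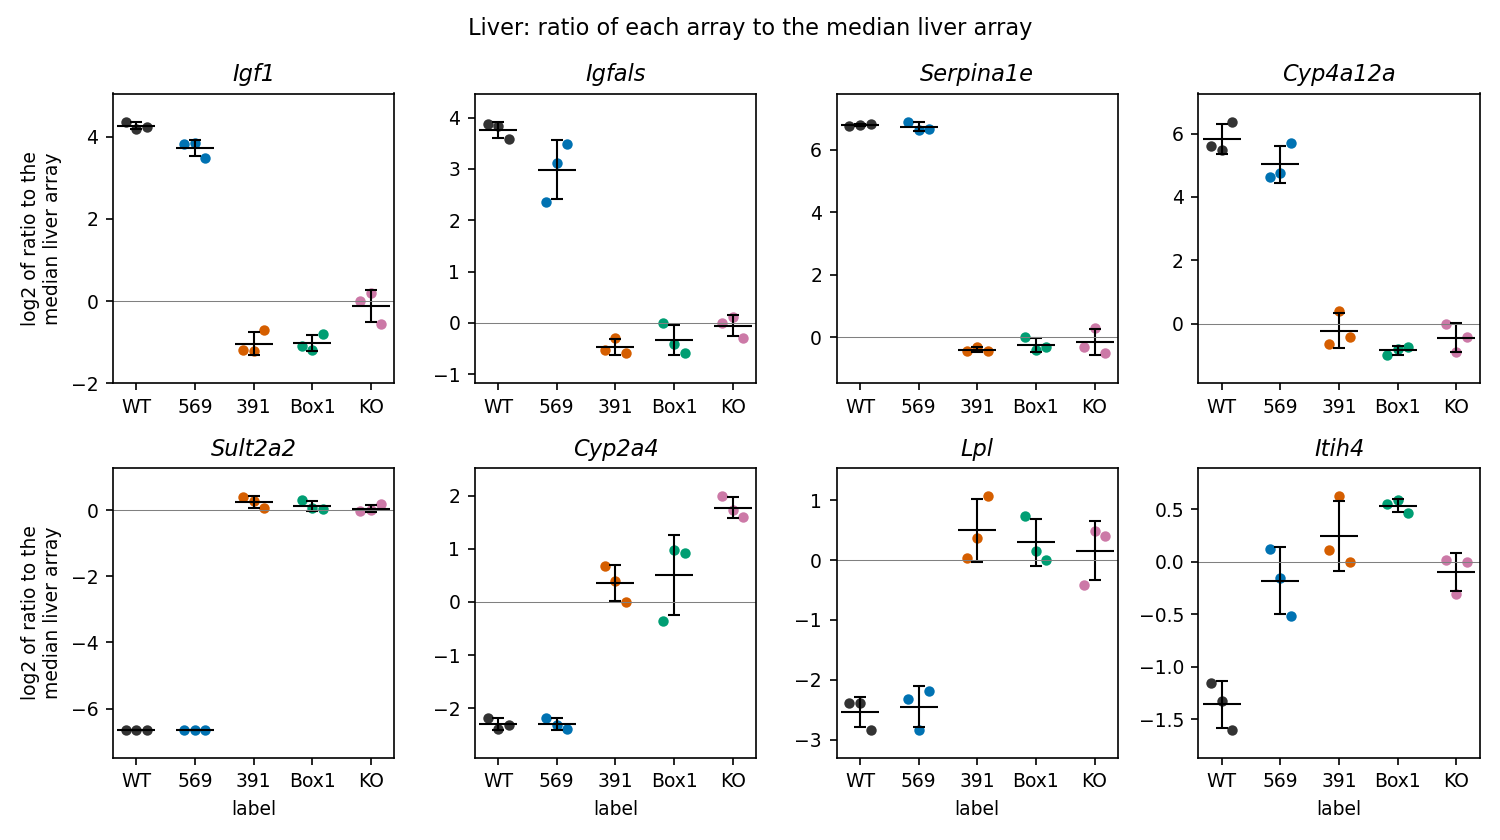
Log2 ratio to the tissue median of 8 genes in the 15 liver arrays, by genotype label (x axis), with a point per array and bars for the mean ± SD of 3 arrays. Igf1 stood at 4.27 ± 0.09 in WT and −1.04 ± 0.28 in 391, and Serpina1e at 6.78 ± 0.03 and −0.40 ± 0.07.

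Liver of the Box1 mutant against WT asks what is lost when JAK2 cannot be activated. Igf1 fell by 5.30 ± 0.18 in the arrays labelled Box1 (−1.03 ± 0.19, adjusted p = 8.6e-11), and so did Igfals (−4.10 ± 0.22, adjusted p = 3.7e-08), Socs2 (−2.50 ± 0.43, adjusted p = 0.0084) and Cish (−1.88 ± 0.43, adjusted p = 0.044). Igfbp1 rose by 3.91 ± 0.81 (adjusted p = 0.029) and Igfbp2 by 1.15 ± 0.24 (adjusted p = 0.029). Of 21 axis genes, 4 rose and 5 fell (6 and 7 adjusted over the list alone; camera adjusted p = 0.0013; adjusted p = 0.3 with an estimated correlation). Of 18 male-biased genes, 9 fell and 0 rose (13 and 1 adjusted over the list alone), with Serpina1e at −7.02 ± 0.16 (adjusted p = 7.3e-13), Cyp4a12a at −6.68 ± 0.32 (adjusted p = 7.2e-09) and Mup2 at −4.32 ± 0.33 (adjusted p = 2.6e-06). The list median was −2.05 (camera adjusted p = 3.1e-36; adjusted p = 0.0011 with an estimated correlation).

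Of 26 female-biased genes, 10 rose and 0 fell in the arrays labelled Box1 (11 and 0 adjusted over the list alone; camera adjusted p = 1.4e-10; adjusted p = 0.0011 with an estimated correlation), among them Sult2a2 by at least 6.20, Cyp2b13 by 6.61 ± 1.17 (adjusted p = 0.011) and Hao2 by 2.03 ± 0.17. In fatty acid uptake, 4 of 22 rose (7 adjusted over the list alone), with Lpl up by 2.84 ± 0.28 and Vldlr by 2.42 ± 0.26 (list adjusted p = 4.2e-04; adjusted p = 0.3 with an estimated correlation). The lipogenic enzymes Scd2 and Elovl6 rose by 1.56 (adjusted p = 0.014) and 1.08 (adjusted p = 0.013), and 3 of 19 genes of fatty acid synthesis rose by either adjustment, over all probes or adjusted over the list alone (list adjusted p = 0.028; adjusted p = 0.62 with an estimated correlation). In gluconeogenesis and fasting response 2 of 17 rose, Foxo1 and Lpin1 (9 adjusted over the list alone; list adjusted p = 7.7e-06; adjusted p = 0.3 with an estimated correlation). In oxidative phosphorylation 2 of 33 rose, Cox5b and Ndufb8 (19 adjusted over the list alone; list adjusted p = 2.1e-10; adjusted p = 0.41 with an estimated correlation). Of 20 acute phase proteins 5 rose and 0 fell (7 and 2 adjusted over the list alone), Itih4 by 1.89 ± 0.17 (list adjusted p = 0.011; adjusted p = 0.67 with an estimated correlation).

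Smaller list shifts in the arrays labelled Box1 were upward in fatty acid oxidation (0 of 27 members called, 4 adjusted over the list alone; adjusted p = 0.027; adjusted p = 0.67 with an estimated correlation) and in glutathione and xenobiotic enzymes, where Gsta4 and Gstt3 rose by 0.99 and 1.71 (6 of 22 up adjusted over the list alone; list adjusted p = 0.028; adjusted p = 0.67 with an estimated correlation). The macrophage markers were higher with 0 of 21 called by either adjustment, the one adjusted over the list alone included (adjusted p = 0.049; adjusted p = 0.67 with an estimated correlation), and the epithelial markers lower, with Sox9, a factor of bile duct cells, down as the 1 of 14 called by either adjustment, the one adjusted over the list alone included (adjusted p = 0.028; adjusted p = 0.3 with an estimated correlation). The immediate early gene Egr1 rose by 2.51 (adjusted p = 0.036), as 1 of 14 in its list (2 adjusted over the list alone; list adjusted p = 0.058). In total 493 probes rose and 123 fell between Box1 and WT, 109 and 73 of them at least 2-fold, for 454 named genes. The slides differed between these groups and could not be fitted as a block. The count of 616 was 321, 280 and 273 without Box1 replicate 1, 2 and 3, 984, 285 and 251 without WT replicate 1, 2 and 3, 974 with array weights, and 1110 in a fit of these 6 arrays alone.

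Liver of the knockout against WT asks what is lost without any receptor. Igf1 fell by 4.39 ± 0.18 in the arrays labelled KO (−0.12 ± 0.39, adjusted p = 1.2e-09), and so did Igfals (−3.83 ± 0.22, adjusted p = 1.2e-07) and Socs2 (−2.73 ± 0.43, adjusted p = 0.0032). Cish (−1.74, adjusted p = 0.051), Igfbp1 (2.47, adjusted p = 0.17) and Igfbp2 (0.97, adjusted p = 0.053) did not pass the test. Igfbp3 was not called in KO (0.46, adjusted p = 0.32), in 391 (−0.32, adjusted p = 0.56) or in Box1 (0.15, adjusted p = 0.84). Of 21 axis genes 1 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.11). Of 18 male-biased genes 11 fell and 1, Selenbp2, rose (12 and 1 adjusted over the list alone), with a median of −2.24 (camera adjusted p = 2.5e-29; adjusted p = 0.0015 with an estimated correlation). Serpina1e fell by 6.94 ± 0.16 (adjusted p = 8.7e-13), Cyp4a12a fell by 6.27 ± 0.32 (adjusted p = 2.2e-08), and Csad, an enzyme of taurine synthesis, fell by 3.25.

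Of 26 female-biased genes 9 rose and 0 fell in the arrays labelled KO by either adjustment, over all probes or adjusted over the list alone (camera adjusted p = 8e-08; adjusted p = 0.0015 with an estimated correlation). Sult2a2 rose by at least 6.11, Cyp2a4 by 4.08 ± 0.27 (adjusted p = 3.8e-07) and Hao2 by 2.28 ± 0.17, while Cyp2b9 stood at ratios of 0.08, 0.1 and 3.4 in the 3 KO arrays (1.23, adjusted p = 0.69). Lpl rose by 2.70 ± 0.28 (adjusted p = 8.2e-05), Vldlr by 2.70 ± 0.26 (adjusted p = 3.3e-05) and Pparg by 1.38 ± 0.17 (adjusted p = 4.2e-04), the 3 of 22 genes of fatty acid uptake that rose (4 adjusted over the list alone; list adjusted p = 0.12). In gluconeogenesis and fasting response 3 of 17 rose (8 adjusted over the list alone), among them Gpt and Klf15 by 0.87 and 1.13 (list adjusted p = 4e-05; adjusted p = 0.3 with an estimated correlation). In oxidative phosphorylation 4 of 33 rose (16 adjusted over the list alone), with Cox5b up by 0.68 and Sdhb by 0.77 (list adjusted p = 2.9e-08; adjusted p = 0.49 with an estimated correlation). Macrophage markers were higher, with Laptm5 the 1 of 21 that rose (4 adjusted over the list alone; list adjusted p = 0.0099; adjusted p = 0.67 with an estimated correlation), and so were lymphocyte markers, with 0 of 15 called over all probes (5 up adjusted over the list alone; list adjusted p = 0.014; adjusted p = 0.45 with an estimated correlation).

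The arrays labelled KO also showed changes in 3 clock genes, Per2, Per3 and Tef, up by 1.98 (adjusted p = 0.014), 1.78 ± 0.36 (adjusted p = 0.017) and 1.34 (adjusted p = 0.005), as 3 of 14 members up (6 up and 3 down adjusted over the list alone; list adjusted p = 0.42). The uridine phosphorylase Upp2 rose by 3.09 ± 0.46 (adjusted p = 0.002). Of 22 glutathione and xenobiotic enzymes 5 rose (7 up and 3 down adjusted over the list alone; list adjusted p = 0.14), Gsta2 by 1.65 and Gsta1 by 1.38. Itih4 and Serpina3n rose by 1.26 and 1.48, and Crp (−0.60) fell, among 20 acute phase proteins (5 up and 1 down adjusted over the list alone; list adjusted p = 0.25). Sox9 fell by 1.08 and was the 1 epithelial marker called by either adjustment, the one adjusted over the list alone included (list adjusted p = 0.092). In total 671 probes rose and 228 fell between KO and WT, 166 and 97 of them at least 2-fold, for 685 named genes. No term for slide could be fitted, since each group lay on 1 slide. The count of 899 was 573, 413 and 514 without KO replicate 1, 2 and 3, and 406 and 500 without WT replicate 2 and 3.

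The remaining list results in the livers labelled 391, Box1 and KO were not called by camera. Bile acid synthesis and transport had Cyp7b1, an oxysterol hydroxylase, as its 1 of 17 members called, down in each (−2.92, −2.81 and −2.81; list adjusted p = 0.6, 0.74 and 0.85; adjusted over the list alone, 1 fell in each, and 1, 0 and 3 rose). Of the erythroid markers Alas2, the erythroid enzyme of haem synthesis, fell in each (−1.38, −1.46 and −1.22; 1 of 5, and 1 adjusted over the list alone). In cholesterol synthesis Srebf2 rose by 0.63 in 391 and 0.66 in Box1 and Tm7sf2 fell by 0.83 in 391, with the same calls adjusted over the list alone and list adjusted p = 0.22, 0.53 and 0.57. In fatty acid synthesis Acaca rose by 0.95 in 391 (1 of 19; 4 adjusted over the list alone; list adjusted p = 0.086) and Fads1 by 0.51 in KO (1 of 19; 3 up and 1 down adjusted over the list alone; list adjusted p = 0.42). Of the interferon and MHC genes Usp18 rose by 1.09 in KO (1 of 21; 6 adjusted over the list alone; list adjusted p = 0.058). Pecam1 rose by 0.65 in 391 as the 1 endothelial marker called by either adjustment, the one adjusted over the list alone included. Btg2 (−0.44) fell in 391 among the immediate early and heat shock genes, and the cell cycle inhibitor Cdkn1a rose by 2.98 in 391 among 15 cell cycle genes (2 up and 1 down adjusted over the list alone). No member of the extracellular matrix list (27 genes) or of the adipocyte markers in liver (6 genes) was called over all probes in any comparison with WT in liver. Adjusted over the list alone, 1 matrix gene fell in 569 and 1 in KO, and 0 adipocyte markers were called. Camera called 31 of the 92 tests in liver, and 6 with an estimated correlation, which were the male-biased and female-biased genes in 391, Box1 and KO.

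The calls of 391, Box1 and KO in liver overlapped. Of the probes that rose, 275 were shared by 391 and Box1 (7.30 for independent lists), 286 by 391 and KO (9.94) and 213 by Box1 and KO (7.09). Of those that fell, 101, 111 and 91 were shared (0.525, 0.973 and 0.601 for independent lists). In all 3 comparisons 171 probes rose and 81 fell, of 1252 and 328 called in at least 1. The differences from WT correlated across probes with r = 0.796, 0.708 and 0.717, where 20 simulations of unchanged groups against the same WT arrays gave 0.501. Probes are not independent replicates. Their covariances were 0.0497, 0.0457 and 0.0443 against 0.00844 simulated, and 71.6, 70.1 and 69.4 percent of probes had the same sign against 66.6 simulated. The 3 WT arrays are too few to split, so part of the excess may come from the shared controls. None of these 3 mutants shared the slide of WT, and 391 and KO shared a slide. A slide difference from WT could thus also raise the overlap and cannot be told apart from genotype.

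Against 569, the truncation at 391 had 2010 probes up and 180 down in liver. Serpina1e (−7.13), the small secreted protein Wfdc21 (−5.75), Mup2 (−5.50), Cyp4a12a (−5.26) and Igf1 (−4.76, adjusted p = 4.9e-10) fell, and Sult2a2 (at least 6.32), Cyp2b13 (5.70, adjusted p = 0.012), Spink1 (4.78), Hamp2 (4.48) and Lpl (2.94) rose. This comparison bears on the receptor segment between both truncation points. The share of rises depended on scaling: after quantile normalization within the tissue 807 probes rose and 214 fell. Slide and genotype cannot be told apart here, and the count of 2190 was 1155 without 391 replicate 1, 698 and 1059 without 569 replicate 2 and 3, 538 in a fit of these 6 arrays alone, and 2412 without the arrays with pancreatic transcripts, which leaves 1 array labelled 391.

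Liver arrays labelled KO and 391 shared a slide, and their comparison asks what the truncated receptor retains. Gdi2, a regulator of Rab proteins in vesicle traffic, was lower in KO by 3.22 (−3.22 ± 0.16, adjusted p = 1.8e-07), with ratios of 0.13, 0.14 and 0.13 in the KO arrays, although 2 other Gdi2 probes stayed near 1. Sugct (−2.72 ± 0.20, adjusted p = 1.1e-05), A1cf, a cofactor of apolipoprotein B mRNA editing (−2.46 ± 0.16, adjusted p = 2.9e-06), and Cdkn1a (−3.39 ± 0.58, adjusted p = 0.029) were also lower in KO. BC018473 (1.94 ± 0.14, adjusted p = 1.1e-05), Ugt1a10 (2.25, adjusted p = 0.028), Ces3a (2.04 ± 0.34, adjusted p = 0.027), Cyp2a4 (1.42, adjusted p = 0.047) and Hao2 (1.02, adjusted p = 0.024) were higher in KO. Igf1 differed by 0.92 (adjusted p = 0.06). In total 46 probes were higher and 38 lower in KO, for 66 named genes, and after quantile normalization 56 were higher and 70 lower. The count of 84 was 27 without 391 replicate 2 or without KO replicate 2, 37 without KO replicate 1, 271 without 391 replicate 3, and 173 (46 higher, 127 lower, 43 shared) without the 2 arrays with pancreatic transcripts, which leaves 1 array labelled 391.

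Liver arrays labelled KO and Box1 were compared to ask what the Box1 mutant receptor retains. Gdi2 (−3.22, adjusted p = 8.9e-08), Sugct (−3.12, adjusted p = 1.1e-06), A1cf (−2.67, adjusted p = 5.9e-07) and Csad (−1.98, adjusted p = 0.01) were lower in KO. Abhd1 (2.38, adjusted p = 1.1e-05), Ghr by its first probe (2.28, adjusted p = 2.9e-04), BC018473 (1.88, adjusted p = 1.1e-05) and Ces3a (1.91, adjusted p = 0.043) were higher. In total 30 probes were higher and 39 lower, for 53 named genes. These groups lay on different slides, and the count of 69 was 31 without Box1 replicate 2 or 3, 44 and 33 without KO replicate 1 and 2, and 240 after quantile normalization. Over all genotypes, limma's moderated F test called 2533 liver probes, and 1297 without 569 replicate 2.

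**Figure D2:**
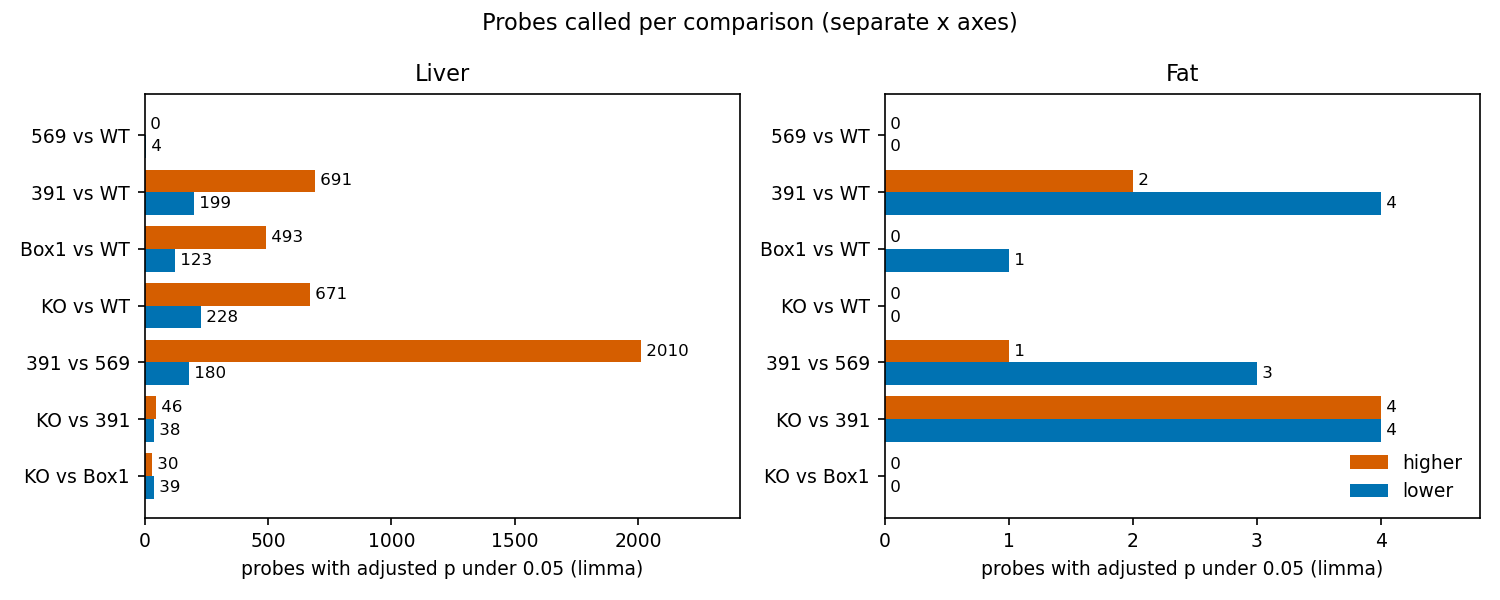
Number of probes called (x axis; adjusted p under 0.05 of 46643 probes) in each comparison (y axis) in liver and in fat, on separate scales, with higher probes in orange and lower probes in blue. In liver 691 probes rose and 199 fell for 391 against WT, and in fat 2 rose and 4 fell.

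Fat arrays differed in transcripts of other tissues. The median of 18 skeletal muscle markers lay at 3.58 in 569 replicate 1, 4.72 in 569 replicate 3, 4.31 in Box1 replicate 3 and 3.47 in KO replicate 2, and between −2.17 and 1.65 in each other fat array. Lymphocyte markers were low in these 4 arrays (−2.12, −2.18, −2.06 and −1.89), in 569 replicate 2 (−1.94), KO replicate 3 (−1.69) and WT replicate 2 (−1.60), and hepatocyte markers were high in Box1 replicate 2 (3.90) and WT replicate 2 (2.21). The adipocyte genes lay at −2.32 in 569 replicate 3. Permutation tests of these medians over the 5 labels gave p = 0.394 for muscle, 0.144 for lymphocyte, 0.506 for hepatocyte and 0.853 for adipocyte genes (adjusted over these 4: 0.675, 0.574, 0.675 and 0.853), with 100000 resamples. The array labelled 569 replicate 3 also had the widest ratios, with 0.16 and 3.52 at the first and the 99th percentile, and its array weight was 0.227.

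**Figure D3:**
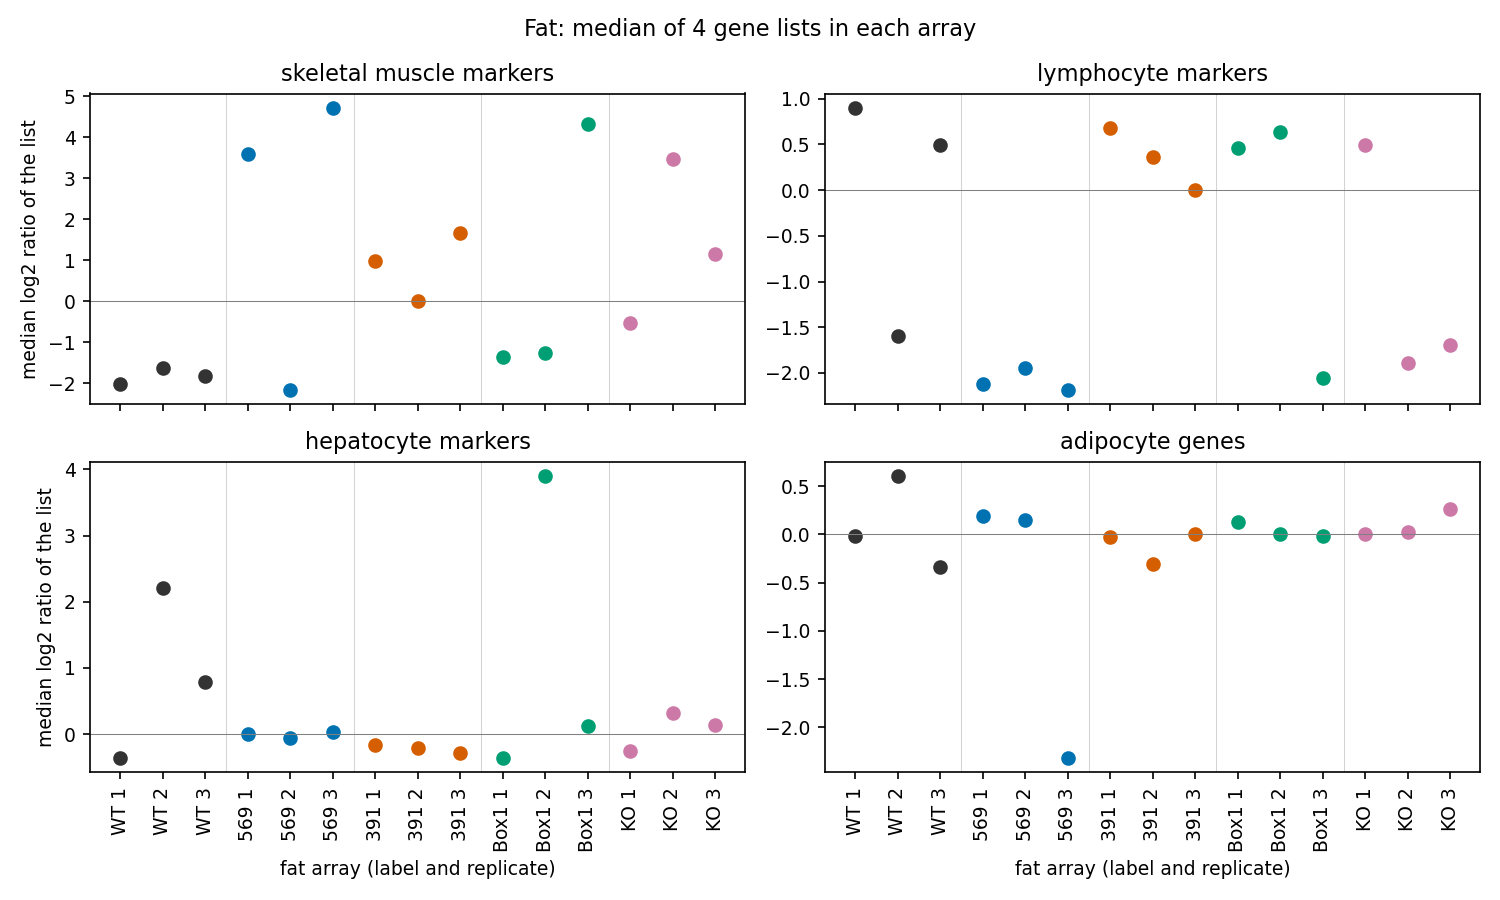
Median log2 ratio (y axis) of the skeletal muscle, lymphocyte, hepatocyte and adipocyte lists in each of the 15 fat arrays, a point per array, by genotype label (x axis). The muscle list lay at 4.72 in 569 replicate 3 and at −2.17 in 569 replicate 2.

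In fat of the 569 truncation limma called 0 probes against WT, with 4178 at an unadjusted p under 0.05. Igf1 stood at 0.87 ± 2.10 in 569 and 1.15 ± 0.42 in WT, and Igfals at 1.18 ± 0.38 and 1.45 ± 0.50. Among the lists, skeletal muscle markers were higher (median 4.16, camera adjusted p = 4.3e-07) and so was oxidative phosphorylation (0.40, adjusted p = 9e-05). Lymphocyte markers (−2.20, adjusted p = 2e-06), interferon and MHC genes (−0.77, adjusted p = 0.0053), adipocyte genes (−0.88, adjusted p = 0.0089), cell cycle genes (adjusted p = 0.0087) and fatty acid synthesis (−0.73, adjusted p = 0.021) were lower. Each of these 7 had adjusted p = 0.99 with an estimated correlation. In 569 replicate 3 the list medians were −2.32 for adipocyte genes, −1.22 for fatty acid synthesis, −1.79 for interferon and MHC genes and 0.93 for oxidative phosphorylation, and between −0.09 and 0.19 in the other 569 arrays. No member of any list was called over all probes; adjusted over the list alone, 4 of 21 interferon and MHC genes fell and 1 immediate early gene rose. Both groups shared a slide. The count of 0 was 6, 2 and 1 without 569 replicate 2, 569 replicate 3 and WT replicate 2.

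In fat of the 391 truncation, Sctr, the secretin receptor, fell by 2.22 ± 0.22 against WT (1.59 ± 0.19 in WT, −0.62 ± 0.21 in 391, adjusted p = 0.0081). Gdi2 fell by 2.96 ± 0.35 (adjusted p = 0.029), with ratios of 0.15, 0.09 and 0.1 in the 391 arrays, and Pttg1, a securin of the cell cycle, fell by 1.83 ± 0.16 (adjusted p = 0.0045). Adat2, a tRNA deaminase, rose by 1.26 ± 0.16 (adjusted p = 0.042), a call lost in each of 6 refits without 1 array. Igf1 differed by −1.17 (adjusted p = 1) and Igfals by −1.40 (adjusted p = 0.37). Muscle markers were higher (2.64, camera adjusted p = 1e-05), and hepatocyte markers (−1.25, adjusted p = 0.0064) and epithelial markers (adjusted p = 0.0073) lower, each at adjusted p = 0.99 with an estimated correlation. Of the list members 0 were called over all probes, and adjusted over the list alone 1 of 21 axis genes fell and 1 erythroid marker and 2 clock genes rose. In total 2 probes rose and 4 fell, and 11 rose and 13 fell after quantile normalization. Slide and genotype cannot be told apart here, and the count of 6 was 2, 0, 0 and 1 without 391 replicate 1, 391 replicate 2, WT replicate 1 and WT replicate 2, and 16 without 569 replicate 3.

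In fat of the Box1 mutant, Sctr fell by 2.05 (adjusted p = 0.038) and was the 1 probe called against WT, with 2118 at an unadjusted p under 0.05. Igf1 differed by −1.58 (adjusted p = 1) and Igfals by −2.08 (adjusted p = 0.11). Muscle markers were higher (1.97, camera adjusted p = 8.1e-04), and epithelial markers (adjusted p = 0.0062), interferon and MHC genes (adjusted p = 0.014) and fatty acid synthesis (adjusted p = 0.025) lower, each at adjusted p = 0.99 with an estimated correlation. Slide and genotype cannot be told apart here, and the count of 1 was 0 without Box1 replicate 1, WT replicate 1 or WT replicate 3, and 2 without Box1 replicate 2 or 569 replicate 3.

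In fat of the knockout limma called 0 probes against WT, with 2912 at an unadjusted p under 0.05. Sctr differed by −1.78 (adjusted p = 0.086), Igf1 by −1.35 (adjusted p = 0.84) and Igfals by −2.03 (adjusted p = 0.086). Muscle markers were higher (3.40, camera adjusted p = 3e-04). So were immediate early and heat shock genes (0.50, adjusted p = 1.6e-04) and clock genes (adjusted p = 0.032). Lymphocyte markers (−0.97, adjusted p = 2.8e-04), epithelial markers (adjusted p = 0.021), interferon and MHC genes (adjusted p = 0.021) and cell cycle genes (adjusted p = 0.04) were lower. Each had adjusted p = 0.99 with an estimated correlation. No list member was called over all probes in KO or in Box1. Adjusted over the list alone, 1 of 21 axis genes fell and 1 muscle marker and 1 gene of fatty acid uptake rose in each. In Box1 2 immediate early genes rose, and 1 immediate early gene and 1 erythroid marker rose in KO. The count of 0 was 44 without 569 replicate 3, 1 without WT replicate 2, 41 after quantile normalization and 40 with array weights. Camera called 21 of 80 list tests in fat and 0 with an estimated correlation. The axis genes, cholesterol synthesis, fatty acid uptake, fatty acid oxidation, thermogenic genes, extracellular matrix, macrophage, erythroid and endothelial markers were called in no comparison with WT in fat.

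Between the mutants in fat, KO against 391 had Gdi2 (3.24, adjusted p = 0.0096), Pttg1 (1.67, adjusted p = 0.0062) and the transporter Abca5 (1.43 ± 0.15, adjusted p = 0.0083) higher, and Adat2 (−1.22, adjusted p = 0.037), Thg1l (−0.97, adjusted p = 0.031) and Fmr1 (−0.87, adjusted p = 0.037) lower in KO. In total 4 probes were higher and 4 lower in KO, and 50 and 31 after quantile normalization. The 391 arrays had lower Sctr (−2.25, adjusted p = 0.007), Gdi2 (−2.88, adjusted p = 0.033) and Pttg1 (−2.11, adjusted p = 8.9e-04) than 569, as 3 of 4 probes called with 1 higher, and 22 were higher and 19 lower after quantile normalization. KO and Box1 differed in 0 probes in limma (1202 at an unadjusted p under 0.05), and the F test over all genotypes called 7. The 391 and KO arrays shared a slide. Their count of 8 was 4, 0, 5, 0 and 3 without 391 replicate 1, 391 replicate 2, KO replicate 1, KO replicate 2 and KO replicate 3, and 43 without 569 replicate 3. The count for 391 against 569 was 2, 1, 8 and 73 without 391 replicate 2 and 569 replicate 1, 2 and 3. That of the F test was 93 without 569 replicate 3, 4 without 569 replicate 1 or WT replicate 1, 3 without Box1 replicate 1, and 2 without 391 replicate 1, Box1 replicate 3 or any KO replicate.

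The arrays of 391, Box1 and KO were also set together against WT, a contrast chosen after the data were seen. In liver 914 probes rose and 225 fell, 119 and 80 of them at least 2-fold (1139 in all; 339 without WT replicate 2 and 411 without WT replicate 3). In fat Sctr (−2.01 ± 0.19, adjusted p = 0.0024) and Trp63, a factor of stratified epithelium (−1.23, adjusted p = 0.022), fell, and Trp63 was named after its values were seen. Without 569 replicate 3, an array in none of these groups that adds to the common spread, 12 fat probes were called, among them Igf1 (−1.37 ± 0.18, adjusted p = 0.0262) and Igfals (−1.84 ± 0.25, adjusted p = 0.0291). The count of 2 in fat was 0 without WT replicate 2 and 1 without each of the 9 other WT, 391, Box1 and KO arrays except 391 replicate 1 and Box1 replicate 3.

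The difference between tissues was tested for each mutant. For 391, Sult2a2 (at least 6.98, adjusted p = 1.1e-04), Hamp2 (6.96, adjusted p = 0.0102) and Spink1 (5.49, adjusted p = 1.5e-06) rose more in liver than in fat, and Serpina1e (−5.95, adjusted p = 8e-10), Cyp4a12a (−5.51, adjusted p = 1.6e-08) and Ces3a (−5.44, adjusted p = 1.6e-08) were lower by the same contrast. For Box1 the extremes were Sult2a2 (at least 5.33), Spink1 (4.59) and Sult2a1 (4.56) upward and Cyp4a12a (−6.10), Serpina1e (−5.92) and Wfdc21 (−5.58) downward. For KO they were Sult2a2 (at least 6.23), Hamp2 (6.32) and Sult2a1 (4.88) upward and Cyp4a12a (−5.77), Serpina1e (−5.66) and Cyp4a12b (−5.40) downward. In fat alone Sult2a1 differed from WT by 0.11 in Box1 and −0.07 in KO. Cyp4a12a differed there by −0.55, −0.58 and −0.50 in 391, Box1 and KO, and Serpina1e by −1.22, −1.10 and −1.28. A ratio cannot tell a transcript absent from fat from a steady one, so a called contrast may restate the liver difference alone. The contrast called 50 probes up and 56 down for 391, 25 up and 44 down for Box1 (94 and 99 after quantile normalization), and 74 up and 85 down for KO, and limma called 0 for 569 (3614 at an unadjusted p under 0.05). The counts for 391 and KO also grew after quantile normalization, as given in the part on processing. Liver and fat arrays were normalized together for these contrasts. Liver and fat lay on different slides except for Box1. Without fat 569 replicate 3 the counts were 187 for 391, 113 for Box1, 374 for KO and 17 for 569. That for 569 was 441 without fat 569 replicate 2, 14 without fat WT replicate 2, and 1, 1 and 4 without liver WT replicate 1, 2 and 3. That for KO was 86 and 105 without fat WT replicate 1 and 3, 92 and 91 without fat KO replicate 2 and 3, 102 and 96 without liver KO replicate 1 and 2, and 99 without liver WT replicate 2.

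Probes that set 1 genotype apart in 1 tissue were also read in the other tissue, a check chosen after the data were seen. In liver 19 probes set the arrays labelled KO apart from all others by at least 0.5, a bound set after a first look at such probes, among them those of Gdi2, A1cf, Sugct, Abhd1 and Pttg1. In fat their mean signed value was 0.85 ± 0.03 in the arrays labelled 391 and −0.06 ± 0.09 in those labelled KO (exact permutation over 455 splits, 1-sided p = 0.0022, or 0.022 adjusted over 20 such tests). Of the 19 probes, 7 stood apart from all other fat arrays in the 3 labelled 391 (Pttg1, Gdi2, BC018473, Ppfibp1, Per3 and 2 of Abhd1). The other 12 did not. Sugct (ratios of 0.42, 0.37 and 0.44 in the arrays labelled 391) was low there, next to 0.43 in 569 replicate 3. H1f2 (0.47, 0.26 and 0.52) and Nfil3 (0.41, 0.58 and 0.43) were low too, next to 0.52 and 0.51 in WT replicate 3. Slc5a6, higher in liver KO, stood at 1, 1.4 and 1.25, below 1.78 in 569 replicate 1. A1cf (1.11, 1 and 1.19) and the Upp2 probes lay near 1 in all fat arrays. Whether these have signal in fat is unknown, and without it they could not differ between fat arrays. In the other direction, 5 probes that set the fat arrays labelled 391 apart stood at 1.11 ± 0.03 in the liver arrays labelled KO and at −0.06 in those labelled 391 (exact permutation p = 0.0022, adjusted 0.022). The Gdi2 and Pttg1 probes belong to both sets, so the second test is not separate from the first. In each, the p-value is the smallest that 455 splits allow. Pttg1, for instance, had ratios of 0.38, 0.39 and 0.38 in liver KO and 0.35, 0.31 and 0.28 in fat 391. In liver 3 probes (Ghr, the thyroxine carrier Serpina7 and an unnamed one) set the arrays labelled Box1 apart. In fat the unnamed probe had ratios of 19.18 in Box1 replicate 3, 13.15 in KO replicate 2 and 23.27 in KO replicate 3, and between 0.89 and 1.05 in the others. Ghr stood at 0.44, 0.29 and 0.46 in these 3 arrays, next to 0.5 in 391 replicate 2, and Serpina7 at 1.03, 1.12 and 1.05, within the range of the others. The mean of the 3 probes was 1.83, 1.89 and 1.91 there and at most 0.29 in the others, and its gap to the next array, 1.54, was 0.171 without the unnamed probe. Of the 84 probes called between KO and 391 in liver, 66 had the opposite sign in fat, with r = −0.65 across these probes, which are not independent replicates. The contrast of KO with 391 between the tissues called 53 probes up and 76 down. Its count of 129 was 346 without fat 569 replicate 3, 71 and 80 without fat KO replicate 2 and 3, 73 without liver 391 replicate 2, and 75 and 70 without liver KO replicate 1 and 2. Directions given above for arrays labelled 391, Box1 and KO, in liver as in fat, rest on these labels.

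**Figure D4:**
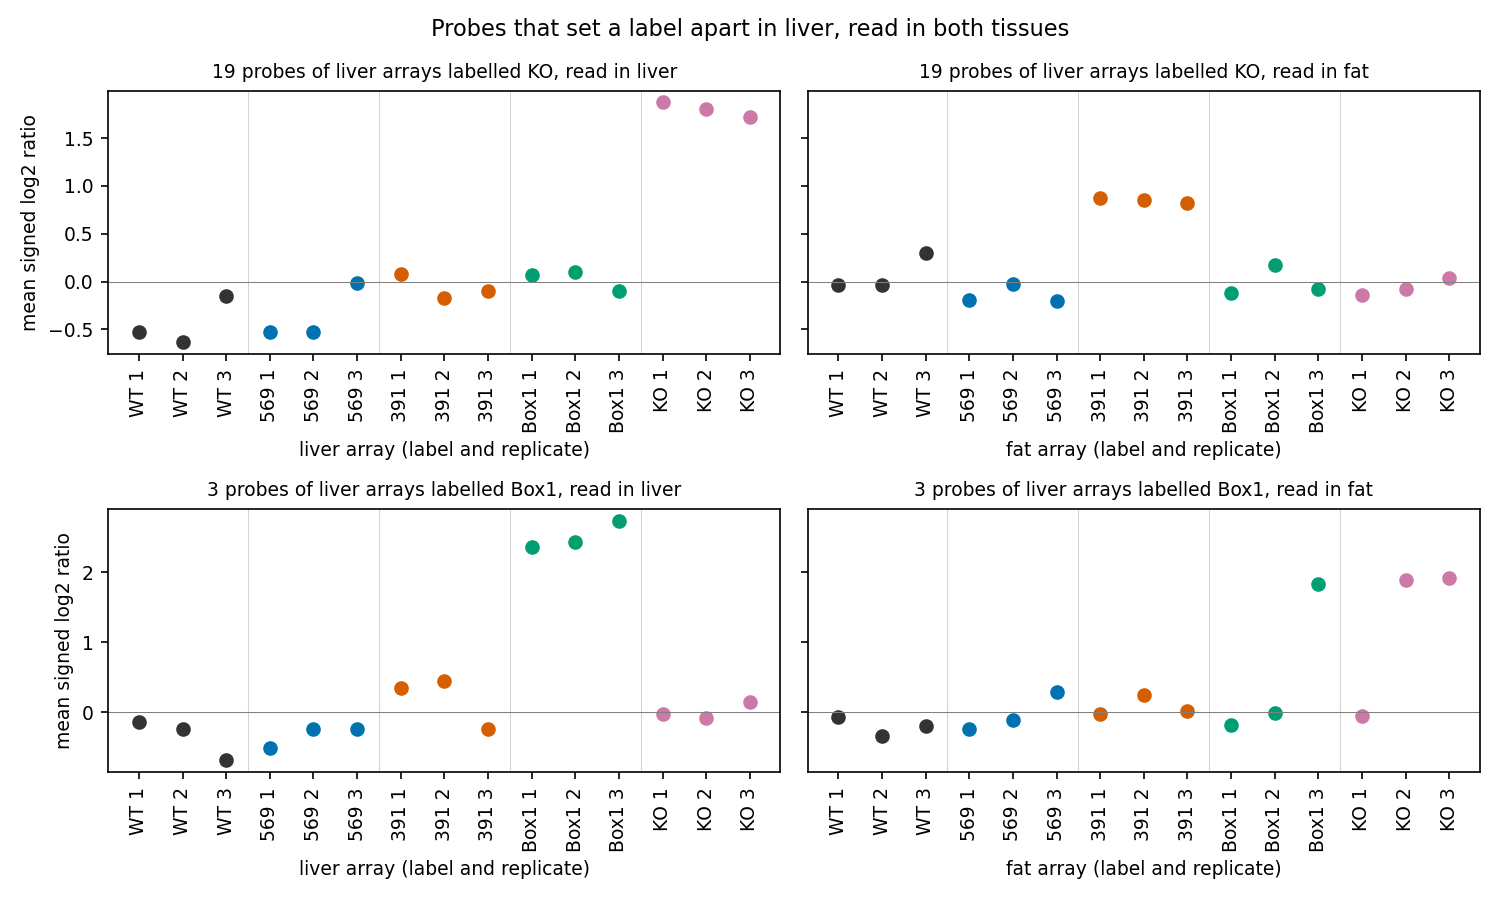
Mean signed log2 ratio (y axis) of the 19 probes that set liver KO apart and of the 3 that set liver Box1 apart, in each liver array and each fat array, a point per array, by genotype label (x axis). In fat the 19 probes lay at 0.85 ± 0.03 in the arrays labelled 391 and at −0.06 ± 0.09 in those labelled KO.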

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

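The tests weighed for the 3 patterns below (mislabelled samples, other tissue, slide, opposite responses, scaling, muscle and genotype) were chosen after the patterns were seen, and so were the contrast of KO with 391 between tissues and that of 391, Box1 and KO together with WT; the counts of splits and the other contrasts were planned.

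Whether the response to a mutant differed between liver and fat was tested on the difference itself. A transcript absent from fat would give such a difference by its change in liver alone. The ratios cannot show which transcripts are absent. For 391 the contrast called 106 probes, led by Serpina1e and Sult2a2, and 4 of 100 splits of the samples gave as many, with 157 as the highest other. For KO it called 159 probes, among them Cyp4a12b and Sult2a1, and 2 of 100 splits gave as many. The highest other split called 487, several times the real count. Some splits keep the real grouping in 1 tissue, so a high count may hold the genotype's own effect. What set that split apart was not tested. For Box1 it called 69 probes, and 7 of 100 splits gave as many (highest 140). Such splits can keep the real liver grouping and change fat alone. The shares for 391, KO and Box1 are thus not those of unrelated groupings and cannot decide whether chance gave the counts. For 569 the count was 0 in limma, all 100 splits gave as many, and another split called 108, the source of which was not tested. The difference between tissues in KO against 391 called 129 probes, and 1 of 100 splits, the real one, gave as many (highest other 18).

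The first pattern is that the mean of 19 liver KO probes was highest in the 3 fat arrays labelled 391, where 7 of them stood apart and 12 did not, and that of 3 liver Box1 probes in fat Box1 replicate 3, KO replicate 2 and KO replicate 3, where it rested mainly on 1 unnamed probe. The 12 include probes near 1 in all fat arrays, such as those of Upp2, which could not stand apart if without signal in fat. Muscle, lymph node or liver tissue in the fat samples is argued against by gaps of 0.212 and 0.573 that stayed after the list medians were fitted, for the Box1 score only through the unnamed probe (−0.267 without it). Slide as the cause is argued against for the KO probes, since fat arrays labelled 391 and KO differed by 0.908 on a shared slide, and an opposite response to the genotype as labelled is argued against for the Box1 probes, since the 3 fat arrays labelled KO spanned 1.97 (1.09 without the unnamed probe). What stays open is a mislabelled set of samples, in liver or in fat, with which gaps of 0.519 and 1.54 to the next array are consistent (0.171 for Box1 without the unnamed probe). A response to KO and 391 that differs between liver and fat also stays open for the KO probes, because the 66 of 84 probes with opposite sign would come from either. No clear opposite move from WT was seen. In fat the mean of the 19 probes was −0.06 ± 0.09 in KO and 0.08 ± 0.19 in WT. In liver the mean of the 5 fat 391 probes was −0.06 in 391 and −0.06 in WT.

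The second pattern is that of the liver probes called under 2-fold for 391, Box1 and KO together against WT, 795 were higher and 145 lower (84.6 percent higher), against 119 higher and 80 lower at 2-fold or more (59.8 percent). No explanation is excluded by the tables. The authors' scaling may account for a part, since after quantile normalization 77.3 percent (95% exact interval 74.5 to 80.02) of the calls under 2-fold were higher, and 40.2 percent of those at 2-fold or more. The interval treats probes as independent, although they share arrays, so it does not measure the uncertainty of this share. Slide and genotype cannot be told apart for it, because only 569 shares the slide of WT. A response of many genes to the loss of receptor signalling stays among the open explanations, as untested.

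The third pattern is that skeletal muscle transcripts differed widely between fat arrays of 1 label. A scaling common to all probes of an array is argued against, since in each array with a muscle median above 3 that median exceeded the 99th percentile of all probes by at least 2.53, while an uneven scaling stays open, since the range of 0.0289 of the array medians was fixed by their common level. Muscle in the dissected fat samples may be the source, but in the array with the fewest, KO replicate 2, 66.7 percent of 18 markers exceeded 1 (log2), between the 80 percent that had been set for it and the share that would have excluded it. Myh4, an abundant myosin of fast muscle, reached ratios of 168.6, 71.24, 46.43 and 25.02 in 569 replicate 3, 569 replicate 1, Box1 replicate 3 and KO replicate 2. Arrays of 1 label spanned 6.89 in 569, which restates the pattern and is no separate test. A genotype that these arrays share cannot by itself give differences between them. Genotype as labelled stays open for the differences between labels (permutation p = 0.394).

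Other splits of the samples were counted for each result. For any difference between genotypes 1 of 100 splits, the real one, gave as many probes in liver (2533, highest other 1691) and in fat (7, highest other 2). In liver a random grouping of the arrays is thus excluded at the share of 0.05. In fat the count of 7 was 2 without 391 replicate 1, Box1 replicate 3 or any KO replicate, as many as the highest other split, so no conclusion is drawn there. Random splits mix the slides, so in neither tissue can they part genotype from slide. For the 3 mutants together 1 of 100 gave as many in liver (1139, highest other 10) and 4 of 100 in fat (2, highest other 10). What gave that fat split several times the real count was not tested. The list tests called as many in 4 of 100 splits in liver (31, highest other 34) and in 69 of 100 in fat (21, highest other 44), so chance cannot be excluded in fat. For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. In liver the real count and the highest other were 4 and 13 for 569 against WT (2 of 10 as large), and, with 1 of 10 as large in each, 890 and 2 for 391, 616 and 1 for Box1, 899 and 1 for KO, 2190 and 1 for 391 against 569, 84 and 2 for KO against 391, and 69 and 0 for KO against Box1. In fat they were 0 and 2 for 569 (10 of 10 as large), 6 and 6 for 391 (2 of 10), 1 and 0 for Box1 (1 of 10), 0 and 0 for KO (10 of 10), 4 and 3 for 391 against 569 (1 of 10), 8 and 0 for KO against 391 (1 of 10), and 0 and 3 for KO against Box1 (10 of 10), where the counts of 0 are limma's, with 4178, 2912 and 1202 probes at an unadjusted p under 0.05.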

How the results depend on the processing

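Of the alternatives below, the pseudocount, the larger-SD probes, the muscle and lymphocyte covariates, the fits without fat 569 replicate 3 where it is in no group compared and those without the pancreatic arrays were chosen after seeing the data. None of the 60 gene results refitted, a part of those named, reversed its direction: 56 kept their direction and side of the threshold under quantile normalization, 59 with array weights, 50 with only the arrays compared and 58 with a pseudocount of 0.1, and of 360 refits without 1 array 278 did and 82 lost the call, in 21 results. No paired analysis was possible because the labels carry no replicate numbers, and the arrays were numbered in accession order. A background or offset alternative and a stricter filter on dim probes were not run, since a ratio holds no level; the fit without a filter is the one reported; and a slide block could not be fitted. What signal over background limits is unknown for the same reason. Counts within 1.5 times of those reported are left out here.

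With only the arrays compared in the fit, which leaves fewer arrays to estimate the spread, liver counts were 260 for 391 against WT, 1110 for Box1, 0 for 569, 538 for 391 against 569, 35 for KO against 391 and 398 for KO against Box1. Fat counts were 0 for Box1, 75 for KO, 225 for 391 against 569, 123 for KO against 391, 1 for KO against Box1 and 6 for 391, Box1 and KO together, and the tissue contrasts gave 109 for Box1, 482 for KO and 325 for KO against 391.

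After quantile normalization the counts were 1021 for 391 against 569 and 240 for KO against Box1 in liver. In fat they were 24 for 391 against WT, 41 for KO, 41 for 391 against 569, 81 for KO against 391, 60 for any genotype and 1 for the 3 mutants together. For the tissue contrasts, liver and fat arrays were normalized together. These contrasts gave 249 for 391, 4 for 569, 193 for Box1, 608 for KO and 478 for KO against 391. The cause was not tested.

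Array weights gave 974 for Box1 in liver, and in fat 2 for Box1, 40 for KO, 28 for KO against 391, 21 for any genotype and 5 for the 3 mutants together; the tissue contrasts gave 3 for 569, 132 for Box1, 628 for KO and 345 for KO against 391. The probes with the larger SD, which are fewer tests, gave 12 for 569, 144 for KO against 391 and 142 for KO against Box1 in liver, 2 for Box1 and 4 for KO against 391 in fat, and 1 for the tissue contrast of 569. With the muscle and lymphocyte medians as covariates fat counts were 0 for Box1, 1 for KO, 2 for 391 against 569, 1 for KO against 391 and 1 for the 3 mutants together. The pseudocount gave 4 for any genotype in fat, the fit without the pancreatic arrays, which leaves 1 array labelled 391, 173 for KO against 391 in liver, and the estimated correlation 6 called lists in liver and 0 in fat (camera; 21 with the preset one). The cause was not tested beyond the number of arrays or probes.

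Leaving out 1 array at a time, liver counts ranged from 0 to 11 for 569 (highest without 569 replicate 3), 379 (WT replicate 2) to 980 (391 replicate 3) for 391, 251 (WT replicate 3) to 984 (WT replicate 1) for Box1, 406 (WT replicate 2) to 873 (WT replicate 1) for KO, 698 (569 replicate 2) to 2451 (569 replicate 1) for 391 against 569, 27 to 271 (391 replicate 3) for KO against 391, 31 to 72 for KO against Box1, 1297 (569 replicate 2) to 3150 (391 replicate 3) for any genotype and 339 (WT replicate 2) to 1439 (391 replicate 2) for the 3 mutants together. Fat counts ranged from 0 to 6 (569 replicate 2) for 569, 0 to 16 for 391, 0 to 2 for Box1, 0 to 44 for KO, 1 (569 replicate 1) to 73 for 391 against 569, 0 to 43 for KO against 391, 2 to 93 for any genotype and 0 (WT replicate 2) to 12 for the 3 mutants together, and the highest counts except that of 569 came without fat 569 replicate 3 (for Box1 also without Box1 replicate 2). The tissue contrasts ranged from 80 to 187 for 391, 0 to 441 (fat 569 replicate 2) for 569, 55 to 113 for Box1, 86 to 374 for KO and 70 to 346 for KO against 391, with the highest of the other 4 without fat 569 replicate 3. In fat that array had a weight of 0.227. KO against Box1 in fat stayed at 0 in limma in all 7 refits (1202 at an unadjusted p under 0.05), and the called lists lay between 27 and 35 in liver and 15 and 26 in fat. Where a group kept 2 arrays or 1, its spread was estimated from all groups.

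The calls lost without 1 array were, in liver, those of Cish (5 of 6 refits), Igfbp2 (4), Lcn2 (4), Igfbp1 (3) and Cyp2b13 (3) for 391, Cyp2b9 (1) and Saa1 (6) for Box1, and Cox5b (5), Foxo1 (4) and Per3 (4) for KO. For 569 they were those of Uhrf1bp1l (5), Wnk4 (4) and Kyat3 (2), and between mutants Cdkn1a (5) and Ces3a (4) for KO against 391 and Psmd8 (5) for KO against Box1. In fat they were Adat2 (6), Sctr (3) and Pttg1 (2) for 391 and Gdi2 (4) and Abca5 (3) for KO against 391. The cause was not tested beyond the number of arrays.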

Other observations

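The test of neighbouring genes was chosen after the results were seen, as were the genes below except Mt1, Serpina12, Slco1a1, Nfil3 and Cyp7a1, which the rule fixed before the data were examined had named.

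Further liver genes are given here one by one, and no test covered them as a group. Bcl6, a repressor that occupies STAT5 sites, rose by 1.87 ± 0.36 (SE, n = 3) in 391 (limma adjusted p = 0.014), 1.94 in Box1 (adjusted p = 0.013) and 1.83 in KO (adjusted p = 0.015). The growth factor receptor Egfr fell in 391 (−2.50, adjusted p = 0.02) and KO (−2.38, adjusted p = 0.025), with −2.15 in Box1 (adjusted p = 0.054). Elovl3, a male-biased fatty acid elongase, fell in each (−3.09, −3.40 and −3.38). So did the complement component C6 (−2.80, −2.82 and −2.61) and the adipokine Serpina12 (−3.88, −3.57 and −4.31). Cyp17a1, a female-biased steroid hydroxylase, rose by 3.44, 2.15 and 3.01. The metallothionein Mt1 rose by 3.46 (adjusted p = 7.4e-04), 2.88 (adjusted p = 0.0036) and 3.42 (adjusted p = 6.8e-04). Mt2 rose by 2.59 in 391 and 2.15 in KO, with 1.42 in Box1 (adjusted p = 0.15). In the livers labelled 569, Serpina12 stood at 1.57 ± 0.78 (SD, n = 3) against 3.53 ± 0.35 in WT (−1.96, adjusted p = 0.13). Slco1a1 stood at 3.12 ± 0.40 (SD) against 4.00 ± 0.27 (−0.88, adjusted p = 0.18). Neither passed the test.

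Beside Per2, Per3 and Tef, 2 more genes with a daily rhythm are given for the livers labelled KO. Values of Cyp7a1, the rate-limiting enzyme of bile acid synthesis, were 1.56 ± 0.18 in KO (SD, n = 3) and −0.13 ± 0.27 in WT (adjusted p = 0.059). Those of Nfil3, a repressor of clock output genes, were −1.22 ± 0.07 and −0.11 ± 0.24 (adjusted p = 0.091). Neither passed the test against WT. The times at which the mice were killed are not given in the sources used here.

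The hypothesis tested here is that variants linked along the chromosome, brought in with the mouse lines, may account for some of the genes that separate the livers labelled KO and 391. Of 63 called genes with a map position, 27 had another called gene of a different family within 50 measured genes, a window and a family rule set after the called genes had been seen in chromosome order. Among 1000 random sets of 63 genes the median was 16, the 95th percentile 24 and the highest 32. The 1-sided permutation p over these sets was 0.021 (0.056 adjusted over 8 comparisons). For KO against Box1 the number was 24 of 48, against a random median of 10 (permutation adjusted p = 0.008). The other 6 sets did not single out KO, but those of all genes called against WT had little room for an excess. They gave 613 of 641 for KO (random median 605, permutation p = 0.119) and 584 of 618 for 391 (random median 580.5, permutation p = 0.316). For Box1, a set without KO arrays, the number was 362 of 408 (random median 348, permutation p = 0.02, adjusted 0.056). The 63 genes with the smallest p against WT gave 13 for KO, 12 for 391 and 16 for Box1, against a random median of 16 in each. The hypothesis thus stays open. After adjustment KO against Box1 passed the threshold and KO against 391 missed it. The 63 genes with the smallest p against WT showed no excess, and the larger sets against WT could hardly show one particular to KO. Genes with related functions can also lie side by side, which was not tested beyond leaving out families of shared name.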
